A study of Homo sapiens with 12 samples.

How the data were processed

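The series holds RNA sequencing of MCF7 and T47D cells, 12 libraries in 4 groups of 3 replicates. Per the labels, cells received 30 pmol of siRNA for 72 hours, and libraries were made with a stranded mRNA kit, a kind that selects RNA with a poly(A) tail. Reads were trimmed with fastp 0.24.0 and aligned to GRCh38 with STAR 2.7.11b, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. The sequence of the siRNA, and whether it was a single siRNA or a pool, are not given either.

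The count values are raw reads per gene in 1 table per line, as deposited by the authors, with no normalization. Each table has 62753 genes and 4 lines of totals that name no gene, which held 14.99 to 19.5% of the reads of a library and were left out. The log2 fold changes and their standard errors are those the authors computed with DESeq2, as deposited, for siNR2C2 against control. The p-value columns, raw and adjusted, are those the authors computed with DESeq2, per the file headers. The signal column holds the mean count over the 6 libraries of a line after division by size factors, per the file headers. The authors' table lists only genes with at least 1 read in each of the 6 libraries, as found from the values, and the design formula is not given. The files hold 12 further per-sample columns that were not used. Authors' values were copied for comparison only.

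Gene symbols came from the authors' table for 17396 genes and from reference names for 25501, matched by gene identifier, and 19856 had none. Positions, strands and transcript parts came from GENCODE 29, in which 15354 of the genes tested in MCF7 and 15199 of those tested in T47D were found.

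The groups, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. In each line, siNR2C2 was compared with siScramble in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15) and a robust quasi-likelihood fit on group alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The difference between lines was the interaction of siRNA and line in a fit over all 12 libraries. Genes called in both lines were compared with the number expected from independent lists by Fisher's exact test, two-sided. These model p-values rest on 3 cultures per group, and a permutation test of 3 against 3 cannot go below p = 0.1. TMM factors lay between 0.985 and 1.008. Errors and p-values cover the spread between cultures.

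The 34 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over lists. Camera with a correlation estimated per list and fry were alternatives. Members were also counted as up, down or not called over all genes, and adjusted over the list alone. No list call held with an estimated correlation.

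In each line the text names NR2C2 and up to 10 genes in each direction with the largest log2 fold change. These had adjusted p under 0.05, a mean of at least 5 CPM, a gene symbol and no overlap between the groups. It also names up to 4 members with the smallest p from each list described, and FOXA1, ESR1, GATA3, PGR, NR2C1 and NR2C2AP whatever their p. For the difference it names 6 genes of each sign with the smallest p, and for both lines 6 of each direction with the largest smaller change, with the same minimum of 5 CPM. If fewer passed, all that passed were named. STAT2 and the lists' deviations per library were added to the comparison between lines after their values were seen.

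Depth was 19446860 to 24952281 reads in genes per library. Pairs of replicates of 1 group differed by 5.75 to 38.4 in chi-square per degree of freedom over genes with at least 20 reads in both, so the spread between cultures exceeds counting error. Pairing of siNR2C2 and siScramble by replicate number is not stated by the submitters. In T47D, libraries of the same number correlated at 0.47, 0.29 and 0.22 after removal of group means, above every other number.

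Alternatives were RLE scaling, no filter and a stricter filter on low counts (1 CPM and 10 reads in 3 libraries), leaving out each library, the replicate number as a block, DESeq2 1.42.0, limma-voom and a fit over all 12 libraries. Leaving out the pair of libraries farthest from their group, and leaving out genes with a particular sequence in the 3' UTR, were added after seeing the data. When a library was left out, the remaining 2 of its group were fitted with the spread pooled over groups.

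The tests were tested on simulated data made from siScramble levels, with known changes put in. Of genes changed 1.5-fold, 2-fold and 4-fold, 62.7%, 80.6% and 95.5% were recovered in MCF7. In T47D 73.1%, 91.04% and 100% were recovered, and for the difference 23.9%, 68.7% and 92.4%. Unchanged genes made up 10.17%, 5.38% and 5.38% of the calls. Both shifted lists were called and 0 others. That 0 is no error rate, since mixed splits of the real libraries called up to 25 lists for the difference.

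For the sequence search, each 7-mer was tested in the 5' UTR, coding sequence and 3' UTR of 1 transcript per gene (that with the longest 3' UTR), by a regression of log2 fold changes on presence of the 7-mer. The regression allowed for length, GC content and level. Fold changes were cut at 2 in log2, parts shorter than 50 bases were left out, and a 7-mer had to occur in at least 50 genes. The search covered 13902 to 16378 7-mers per part and line. A shift of -0.2 put on a known 7-mer in shuffled data ranked first in 10 of 10 runs in each line. This search was chosen after seeing the data. Scripts used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.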

Results

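RNA sequencing was used to ask which transcripts change when NR2C2 is depleted in estrogen receptor-positive breast cancer cells. NR2C2, also called testicular receptor 4, is an orphan nuclear receptor that binds DNA as a transcription factor. MCF7 and T47D are established luminal breast adenocarcinoma lines. In each line, 3 libraries came from cells given 30 pmol of an siRNA against NR2C2 (siNR2C2) and 3 from cells given a scrambled siRNA (siScramble). Cells were harvested after 72 hours. The 12 libraries held 19446860 to 24952281 reads in genes. The series has no library without siRNA. Levels are TMM-scaled CPM, given as mean ± SD with n = 3 libraries per group, and fold changes are siNR2C2 against siScramble.

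NR2C2 (ENSG00000177463, GRCh38 chromosome 3, positions 14947584 to 15053600, plus strand) was lower in each siNR2C2 library than in each siScramble library of the same line. In MCF7 it fell from 66.3 ± 7.01 to 9.41 ± 2.29 CPM, and in T47D from 38.2 ± 2.55 to 5.46 ± 0.348 CPM. The siScramble libraries held 66.00, 73.4 and 59.4 CPM in MCF7 and 36.4, 41.1 and 37.1 CPM in T47D. The siNR2C2 libraries held 10.4, 11.02 and 6.78 CPM in MCF7 and 5.39, 5.83 and 5.15 CPM in T47D. The log2 fold change was -2.82 (SE 0.17) in MCF7 and -2.81 (SE 0.11) in T47D (adjusted p = 6.56e-05 and 1.38e-06 by edgeR with Benjamini-Hochberg adjustment). In the authors' deposited table the log2 fold changes of NR2C2 were -2.82 in MCF7 and -2.80 in T47D. The gene overlaps MRPS25 on the other strand in the annotation.

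**Figure D1:**
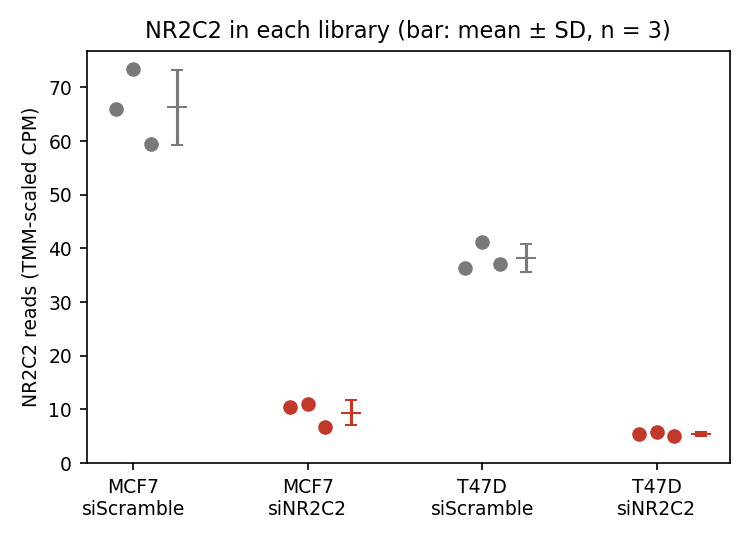
NR2C2 level in each of the 12 libraries, in TMM-scaled CPM on an axis starting at 0, with single libraries as points and bars for the mean and SD of 3. The siNR2C2 libraries lie between 5.15 and 11.02 CPM, below the lowest siScramble library at 36.4 CPM.

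In MCF7, PLAT, the tissue plasminogen activator, rose from 1.15 ± 0.198 to 9.14 ± 1.52 CPM. CYP1A1, a cytochrome P450 that metabolises polycyclic hydrocarbons, rose from 8.44 ± 0.437 to 45.7 ± 10.6 CPM. The transcription factor MAFB rose from 12.7 ± 2.18 to 44.9 ± 3.9 CPM, the chemokine CXCL12, an estrogen receptor target, from 22.95 ± 1.83 to 75.98 ± 3.35 CPM, and the autophagy gene GABARAPL1 from 4.21 ± 0.432 to 13.2 ± 0.975 CPM. ANTXR1, an anthrax toxin receptor, fell from 13.8 ± 0.541 to 2.33 ± 0.248 CPM. SERTAD4 fell from 32.6 ± 0.779 to 7.91 ± 1.36 CPM, the inositol phosphatase MINPP1 from 21.9 ± 1.13 to 5.9 ± 0.447 CPM, and TMEM30A, a subunit of phospholipid flippases, from 178 ± 16.2 to 50.3 ± 3.39 CPM.

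Statistics for these genes in MCF7 were computed by edgeR with Benjamini-Hochberg adjustment. PLAT rose (log2 fold change 2.98, SE 0.21, adjusted p = 8.09e-05), as did CYP1A1 (2.44, SE 0.17, adjusted p = 9.43e-05). MAFB (1.83, SE 0.13, adjusted p = 9.43e-05) and CXCL12 (1.73, SE 0.09, adjusted p = 3.45e-05) rose. GABARAPL1 rose too (1.64, SE 0.14, adjusted p = 2.03e-04). ANTXR1 (-2.56, SE 0.15, adjusted p = 3.47e-05) and SERTAD4 (-2.04, SE 0.13, adjusted p = 7.65e-05) fell. So did MINPP1 (-1.89, SE 0.12, adjusted p = 6.56e-05) and TMEM30A (-1.82, SE 0.09, adjusted p = 3.45e-05). Among the named genes, TRPC6 (2.02, SE 0.31), CDSN (1.75, SE 0.14), DIRAS2 (1.59, SE 0.19), GUCY1A1 (1.56, SE 0.19) and TCHHL1 (1.54, SE 0.22) also rose. The ETS transcription factor ETV4 (-1.84, SE 0.25), the DNA helicase RECQL (-1.72, SE 0.13), and NXPE3 (-1.69, SE 0.16), GALNT12 (-1.62, SE 0.12) and DEPDC1B (-1.58, SE 0.17) also fell. CDSN overlaps PSORS1C1, ETV4 overlaps DHX8 and RECQL overlaps PYROXD1 on the other strand. The strand setting of the counting is not given in the sources used here, so counts of these genes are uncertain.

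Most measured cell cycle genes fell in MCF7. Of 36 measured DNA replication genes, 0 rose, 23 fell and 13 did not pass (0 and 32 over the list alone). Among them CDC45 (-1.23, SE 0.15), TYMS (-1.06, SE 0.14), RFC4 (-0.88, SE 0.12) and GINS2 (-1.47, SE 0.21) fell. For DNA replication genes, camera gave adjusted p = 3.56e-12 (0.64 with an estimated correlation). Of 35 measured mitotic genes, 0 rose, 26 fell and 9 did not pass (0 and 34 over the list alone). Here TOP2A (-1.15, SE 0.08), NUF2 (-0.92, SE 0.11), AURKB (-0.87, SE 0.10) and NDC80 (-0.85, SE 0.09) fell. For mitotic genes, camera gave adjusted p = 1.55e-16 (0.64 with an estimated correlation). The mean log2 deviation of the DNA replication genes from the mean of the line was 0.37, -0.07 and 0.73 in siScramble replicates 1, 2 and 3, and -0.46, -0.37 and -0.21 in siNR2C2.

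Some inflammatory and stress genes rose in MCF7, in 4 lists of which most members did not pass. TNF rose from 0.171 ± 0.169 to 1.45 ± 0.178 CPM, TNFAIP3, an inhibitor of NF-kB signalling, from 1.12 ± 0.275 to 3.74 ± 0.997 CPM, and RELB from 2.35 ± 0.487 to 5.95 ± 1.32 CPM. Of 12 measured NF-kB targets, 3 rose, 0 fell and 9 did not pass (4 and 1 over the list alone). For NF-kB targets, camera gave adjusted p = 0.024 (0.64 with an estimated correlation). Of 24 measured immediate early genes, 10 rose, 0 fell and 14 did not pass (10 and 1 over the list alone), with ATF3 (1.17, SE 0.20) and ZFP36 (0.71, SE 0.08) higher. For immediate early genes, camera gave adjusted p = 0.0087 (0.68 with an estimated correlation). Of 25 measured endoplasmic reticulum chaperones, 9 rose, 1 fell and 15 did not pass (10 and 1 over the list alone). Among chaperones, DNAJB9 (1.43, SE 0.12) and HSPA5 (0.64, SE 0.11) rose, while the disulfide isomerase PDIA3 (-0.91, SE 0.07) fell. For endoplasmic reticulum chaperones, camera gave adjusted p = 0.00235 (0.64 with an estimated correlation). Of 30 measured p53 targets, 6 rose, 1 fell and 23 did not pass (9 and 1 over the list alone), with BTG2 (1.01, SE 0.09) and GADD45A (0.78, SE 0.13) higher. For p53 targets, camera gave adjusted p = 0.0351 (0.688 with an estimated correlation). Leaving out 1 library ended 3 of these calls. The p53 targets had adjusted p = 0.225 without MCF7 siScramble 3, 0.143 without MCF7 siNR2C2 1 and 0.0699 without MCF7 siNR2C2 2. The NF-kB targets had 0.0829 without MCF7 siScramble 3, and the immediate early genes 0.112 without MCF7 siScramble 3. With the stricter filter on low counts the NF-kB targets had adjusted p = 0.0501 (over all alternatives 2.19e-04 to 0.64).

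Some mesenchymal genes rose in MCF7, and most measured ones did not pass. CD44, a hyaluronan receptor, rose from 50.7 ± 10.9 to 108 ± 2.57 CPM, THBS1 from 162 ± 32.6 to 266 ± 3.1 CPM, and SNAI2 from 0.133 ± 0.0599 to 0.812 ± 0.0487 CPM. Of 14 measured mesenchymal genes, 5 rose, 0 fell and 9 did not pass (5 and 0 over the list alone). For mesenchymal genes, camera gave adjusted p = 0.00393 (0.64 with an estimated correlation). Of 15 measured mitochondrially encoded genes, 3 rose, 0 fell and 12 did not pass (3 and 0 over the list alone). Both ribosomal RNAs of the mitochondrion were among those that rose, MT-RNR1 (0.62, SE 0.10) and MT-RNR2 (0.74, SE 0.12). For mitochondrially encoded genes, camera gave adjusted p = 0.00854 (0.688 with an estimated correlation). The mesenchymal call ended at adjusted p = 0.0532 without MCF7 siScramble 3, and the mitochondrial call at 0.112 without MCF7 siScramble 3 and 0.0809 without MCF7 siNR2C2 3.

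Lists of the respiratory chain, mitochondrial ribosome, spliceosome and proteasome were called lower in MCF7 by camera with a preset correlation, while most of their members did not pass. Of 38 measured nuclear-encoded respiratory chain genes, 0 rose, 4 fell and 34 did not pass (0 and 4 over the list alone), with CYC1 (-0.51, SE 0.10) lower. Camera gave this list adjusted p = 3.97e-04 (0.64 with an estimated correlation). Of 35 measured mitochondrial ribosomal proteins, 0 rose, 8 fell and 27 did not pass (0 and 8 over the list alone), with MRPS28 (-1.75, SE 0.21), MRPL4 (-0.59, SE 0.09) and MRPL13 (-0.48, SE 0.09) lower. Camera gave this list adjusted p = 1.01e-04 (0.64 with an estimated correlation). Of 32 measured RNA processing factors, 0 rose, 7 fell and 25 did not pass (0 and 8 over the list alone), with PRPF4 (-0.47, SE 0.07) lower. For RNA processing factors, camera gave adjusted p = 0.00393 (0.64 with an estimated correlation). Of 31 measured proteasome subunits, 0 rose, 8 fell and 23 did not pass (0 and 11 over the list alone), with PSMC2 (-0.33, SE 0.07) lower. For proteasome subunits, camera gave adjusted p = 5.38e-04 (0.68 with an estimated correlation). The median log2 fold changes of these lists were -0.14, -0.18, -0.16 and -0.16. The call on RNA processing factors ended at adjusted p = 0.0516 without MCF7 siScramble 3. That on PSMC2 ended at 0.101 without MCF7 siNR2C2 1 and 0.0674 without MCF7 siNR2C2 2 (over all alternatives 0.00182 to 0.101).

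Lists of the estrogen receptor programme and of metabolism were among those that did not pass camera's test in MCF7. Of 39 estrogen receptor targets, 6 rose, 5 fell and 28 did not pass (median 0.03, adjusted p = 0.341). Of 25 luminal identity genes, 2 rose, 1 fell and 22 did not pass (median 0.04, adjusted p = 0.344). Of 24 receptor coregulators, 4 rose, 1 fell and 19 did not pass (median 0.11, adjusted p = 0.143). Of 32 nuclear receptors, 4 rose, 3 fell and 25 did not pass (median 0.13, adjusted p = 0.356). Of 17 reported NR2C2 targets and partners, 3 rose, 3 fell and 11 did not pass (median 0.07, adjusted p = 0.644). Of 25 apoptosis regulators, 4 rose, 0 fell and 21 did not pass (median 0.05, adjusted p = 0.267). Of 32 interferon-stimulated genes, 0 rose, 2 fell and 30 did not pass (median -0.05, adjusted p = 0.464). Of 24 cholesterol synthesis genes, 1 rose, 6 fell and 17 did not pass (median -0.23, adjusted p = 0.143). Of 32 fatty acid metabolism genes, 1 rose, 4 fell and 27 did not pass (median -0.01, adjusted p = 0.464). Of 28 ATF4 response genes, 1 rose, 0 fell and 27 did not pass (median -0.32, adjusted p = 0.522).

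The remaining lists did not pass in MCF7 either. Of 25 antioxidant genes, 5 rose, 0 fell and 20 did not pass (median 0.05, adjusted p = 0.251). Of 30 hypoxia and glycolysis genes, 1 rose, 0 fell and 29 did not pass (median -0.16, adjusted p = 0.451). Of 58 ribosomal proteins, 1 rose, 0 fell and 57 did not pass (median 0.03, adjusted p = 0.385). Of 30 ribosome assembly genes, 0 rose, 2 fell and 28 did not pass (median -0.12, adjusted p = 0.0600). Of 15 small RNA machinery genes, 3 rose, 3 fell and 9 did not pass (median 0.14, adjusted p = 0.377). Of 28 autophagy and lysosome genes, 5 rose, 1 fell and 22 did not pass (median 0.05, adjusted p = 0.251). Of 18 histone genes, 2 rose, 2 fell and 14 did not pass (median 0.24, adjusted p = 0.251). Of 15 basal epithelial genes, 2 rose, 0 fell and 13 did not pass (median 0.13, adjusted p = 0.196). Of 19 TGF-beta response genes, 6 rose, 0 fell and 13 did not pass (median 0.13, adjusted p = 0.111). Of 6 fibroblast markers, 1 rose, 1 fell and 4 did not pass (median 0.31, adjusted p = 0.251). Of 4 endothelial markers, 0 rose, 1 fell and 3 did not pass (median 0.10, adjusted p = 0.868). Some of these lists passed under alternatives, given with adjusted p and the range over all alternatives in parentheses. They were cholesterol synthesis genes 0.0473 with no filter and 7.45e-04 without MCF7 siScramble 2 (7.45e-04 to 0.762) and ribosome assembly genes 0.0143 with no filter, 0.0282 with a replicate block, 0.0317 without MCF7 siScramble 1, 0.0023 without MCF7 siScramble 2 and 0.00603 without MCF7 siNR2C2 3 (0.0023 to 0.762). Also passing were basal epithelial genes 0.00911 with no filter and 0.00743 without MCF7 siNR2C2 3 (0.00743 to 0.68) and ATF4 response genes 0.0416 without MCF7 siScramble 1 (0.0416 to 0.882). Next came histone genes 0.0159 without MCF7 siScramble 2 (0.0159 to 0.762) and hypoxia and glycolysis genes 0.0116 without MCF7 siNR2C2 2 (0.0116 to 0.882). The endothelial markers had a mean of -0.14 and an upward direction in the test. Of the blood cell markers only CD74 was measured, so that list had no test. The most abundant markers of other cell types in siScramble were COL5A1 at 52.6 CPM, ENG at 5.45 CPM and CD74 at 0.484 CPM. ATF4 response genes stood apart in siScramble replicate 2, with a mean log2 deviation of 0.72. Hypoxia genes were high in both replicates 2, at 0.51 in siScramble and 0.39 in siNR2C2, and at -0.40 to -0.02 in the others.

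In MCF7, 2280 of 15825 tested genes changed at adjusted p under 0.05 by edgeR with Benjamini-Hochberg adjustment, 1132 higher and 1148 lower. Of these, 323 changed by at least 2-fold, 203 higher and 120 lower. The groups did not overlap in 34.995% of tested genes, where chance gives 10%. The count was 1199 without MCF7 siScramble 1, 4199 without MCF7 siScramble 2, 782 without MCF7 siNR2C2 1, 1294 without MCF7 siNR2C2 2 and 919 without MCF7 siNR2C2 3. Without these libraries in turn, 538, 2018, 345, 632 and 430 genes were higher, and 661, 2181, 437, 662 and 489 lower. Those changed by at least 2-fold numbered 204 without MCF7 siNR2C2 1 and 208 without MCF7 siNR2C2 3. The 12 called lists became 6 when leaving out MCF7 siScramble 3.

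In T47D, interferon-stimulated genes fell by large factors. OAS1, a sensor of double-stranded RNA, fell from 56.8 ± 9.9 to 4.03 ± 1.1 CPM, and the antiviral GTPase MX1 from 329.9 ± 67.5 to 31.99 ± 4.59 CPM. IFI6 fell from 152 ± 40.5 to 11.5 ± 4.06 CPM, IFIT1 from 162 ± 47.9 to 14.7 ± 0.902 CPM, and STAT2, a transcription factor of the interferon pathway, from 79.9 ± 2.68 to 25.1 ± 0.586 CPM. The genes IFI27 (-3.93, SE 0.27), OAS2 (-3.17, SE 0.16), ISG15 (-2.92, SE 0.21) and DDX60 (-2.82, SE 0.16) fell as well. Of 41 measured interferon-stimulated genes, 0 rose, 38 fell and 3 did not pass (1 and 38 over the list alone). The list's median log2 fold change was -2.10. For interferon-stimulated genes, camera gave adjusted p = 7.35e-28 (0.267 with an estimated correlation). The log2 fold changes by edgeR with Benjamini-Hochberg adjustment were -3.82 (SE 0.20) for OAS1 (adjusted p = 2.98e-06), -3.37 (SE 0.17) for MX1 (adjusted p = 2.32e-06) and -1.67 (SE 0.08) for STAT2 (adjusted p = 2.32e-06). IFIT1 overlaps LIPA on the other strand.

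**Figure D2:**
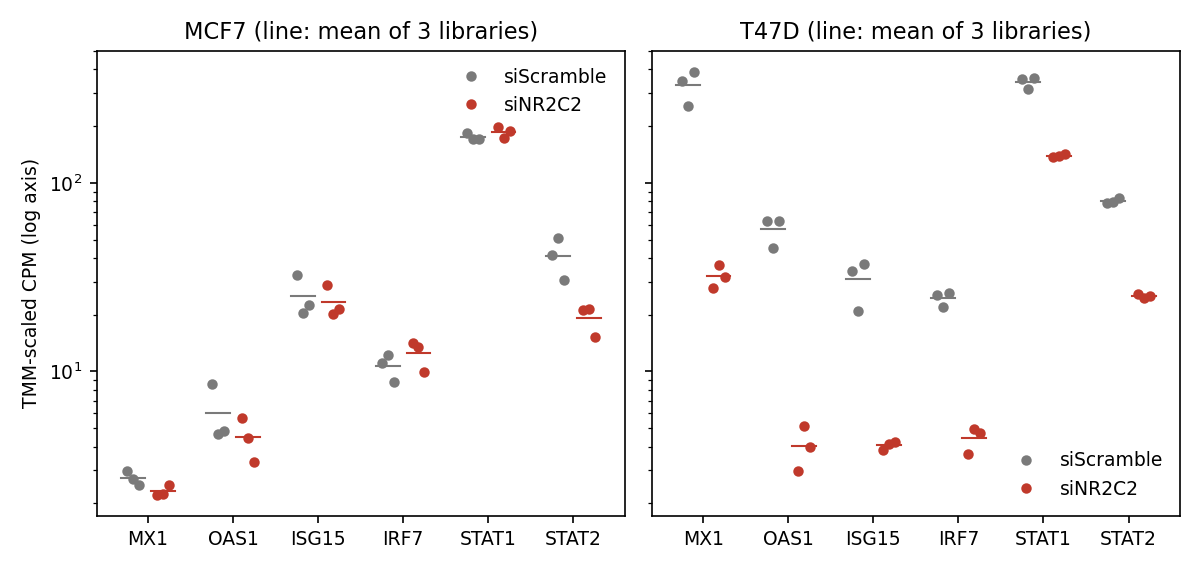
Levels of interferon-pathway genes in each library of MCF7 and T47D, in TMM-scaled CPM on a log axis, with single libraries as points and lines for means of 3. In T47D the mean of MX1 goes from 329.9 to 31.99 CPM, and in MCF7 it is 2.72 and 2.32 CPM.

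Other genes also changed by large factors in T47D. ANTXR1 fell from 9.82 ± 1.9 to 1.22 ± 0.448 CPM. RESF1, a regulator of retroelement silencing, rose from 20.9 ± 0.554 to 83.4 ± 4.88 CPM. The genes SRARP (2.29, SE 0.17), H2AC13 (2.03, SE 0.17), SYNPO (1.95, SE 0.17), PDCD4-AS1 (1.92, SE 0.14), FYB2 (1.85, SE 0.21) and PCDH7 (1.74, SE 0.13) rose, as did the gap junction connexin GJA1 (1.84, SE 0.14), the actin-bundling FSCN1 (1.80, SE 0.17) and the cadherin CDH10 (2.22, SE 0.40). RESF1 had adjusted p = 1.59e-06, SRARP 2.07e-05 and CDH10 0.0032 by edgeR with Benjamini-Hochberg adjustment. With no filter on low counts CDH10 had adjusted p = 0.13 (over all alternatives 2.51e-19 to 0.13). PDCD4-AS1 lies antisense to PDCD4 and H2AC13 belongs to a family of near-identical genes, so both counts are uncertain.

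Most measured cell cycle genes fell in T47D too. Of 35 measured mitotic genes, 0 rose, 28 fell and 7 did not pass (0 and 32 over the list alone), with TOP2A (-1.04, SE 0.12), FOXM1 (-0.93, SE 0.11), CDK1 (-0.78, SE 0.10) and UBE2C (-0.72, SE 0.09) lower. For mitotic genes, camera gave adjusted p = 7.23e-12 (0.267 with an estimated correlation). Of 36 measured DNA replication genes, 1 rose, 22 fell and 13 did not pass (1 and 25 over the list alone), with GINS1 (-1.39, SE 0.15), CDC6 (-0.77, SE 0.12), RRM2 (-0.75, SE 0.11) and E2F1 (-0.68, SE 0.09) lower. For DNA replication genes, camera gave adjusted p = 3.85e-08 (0.658 with an estimated correlation). Most measured ATF4 response genes, which handle amino acid supply, also fell. Of 29 measured ATF4 response genes, 1 rose, 18 fell and 10 did not pass (1 and 20 over the list alone), with SLC7A11 (-1.20, SE 0.15), TRIB3 (-0.89, SE 0.10), CEBPG (-0.60, SE 0.08) and GARS1 (-0.60, SE 0.08) lower. For ATF4 response genes, camera gave adjusted p = 7.43e-06 (0.267 with an estimated correlation). SREBF2, the transcription factor of sterol synthesis, fell from 215 ± 17.1 to 85.6 ± 11.1 CPM, and the enzymes SQLE (-0.72, SE 0.09), HMGCR (-0.64, SE 0.09) and FDPS (-0.58, SE 0.09) fell as well. Of 24 measured cholesterol synthesis genes, 0 rose, 12 fell and 12 did not pass (1 and 13 over the list alone). For cholesterol synthesis genes, camera gave adjusted p = 0.00607 (0.754 with an estimated correlation). In a fit over all 12 libraries SLC7A11 had adjusted p = 0.0831 (over all alternatives 1.04e-22 to 0.0831).

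Estrogen receptor targets rose more often than they fell in T47D. Of 39 measured estrogen receptor targets, 16 rose, 5 fell and 18 did not pass (18 and 5 over the list alone), with TFF3 (1.36, SE 0.16), CXCL12 (0.85, SE 0.09) and HSPB8 (0.73, SE 0.08) higher and RAB31 (-1.28, SE 0.16) lower. For estrogen receptor targets, camera gave adjusted p = 0.0282 (0.901 with an estimated correlation). Of 24 measured receptor coregulators, 3 rose, 0 fell and 21 did not pass (1 and 0 over the list alone), with NCOA3 (0.59, SE 0.10) higher. For receptor coregulators, camera gave adjusted p = 0.0399 (0.952 with an estimated correlation). Of 18 measured TGF-beta response genes, 8 rose, 2 fell and 8 did not pass (10 and 3 over the list alone), with CDKN2B (1.17, SE 0.14), BAMBI (0.73, SE 0.12), PMEPA1 (0.63, SE 0.10) and TGFBR1 (0.61, SE 0.08) higher. For TGF-beta response genes, camera gave adjusted p = 0.037 (0.883 with an estimated correlation). With the replicate number as a block the TGF-beta list had adjusted p = 0.0754, and with no filter on low counts 0.0692 (over all alternatives 0.00857 to 0.883). Leaving out 1 library ended each of these calls. The estrogen receptor targets had adjusted p = 0.102 without T47D siScramble 1 and 0.157 without T47D siNR2C2 2. The coregulators had 0.12 without T47D siScramble 1, 0.0949 without T47D siScramble 2, 0.22 without T47D siNR2C2 2 and 0.213 without T47D siNR2C2 3. The TGF-beta list had 0.0961 without T47D siScramble 1, 0.129 without T47D siNR2C2 2 and 0.102 without T47D siNR2C2 3.

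Some histone genes, most of whose transcripts lack a poly(A) tail, rose in T47D. Of 18 measured histone genes, 8 rose, 1 fell and 9 did not pass (8 and 2 over the list alone), with H3C10 (1.56, SE 0.11), H4C8 (1.53, SE 0.14), H1-2 (1.22, SE 0.14) and H2AC6 (1.15, SE 0.11) higher. For histone genes, camera gave adjusted p = 0.0118 (0.883 with an estimated correlation). Of 58 measured ribosomal proteins, 1 rose, 0 fell and 57 did not pass (0 and 0 over the list alone), with RPL10 (0.34, SE 0.09) higher. For ribosomal proteins, camera gave adjusted p = 0.00712 (0.952 with an estimated correlation). Reads of both families can be split among near-identical copies. The mean log2 deviation in siNR2C2 replicates 1, 2 and 3 was 0.40, 0.10 and 0.10 for histones and 0.36, -0.05 and -0.08 for ribosomal proteins. The histone call ended at adjusted p = 0.0521 without T47D siNR2C2 1. The ribosomal protein call ended at 0.0541 without T47D siScramble 2 and 0.649 without T47D siNR2C2 1. The call on RPL10 ended at 0.0823 without T47D siScramble 2 and 0.0824 without T47D siScramble 3 (over all alternatives 1.79e-05 to 0.0824).

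**Figure D3:**
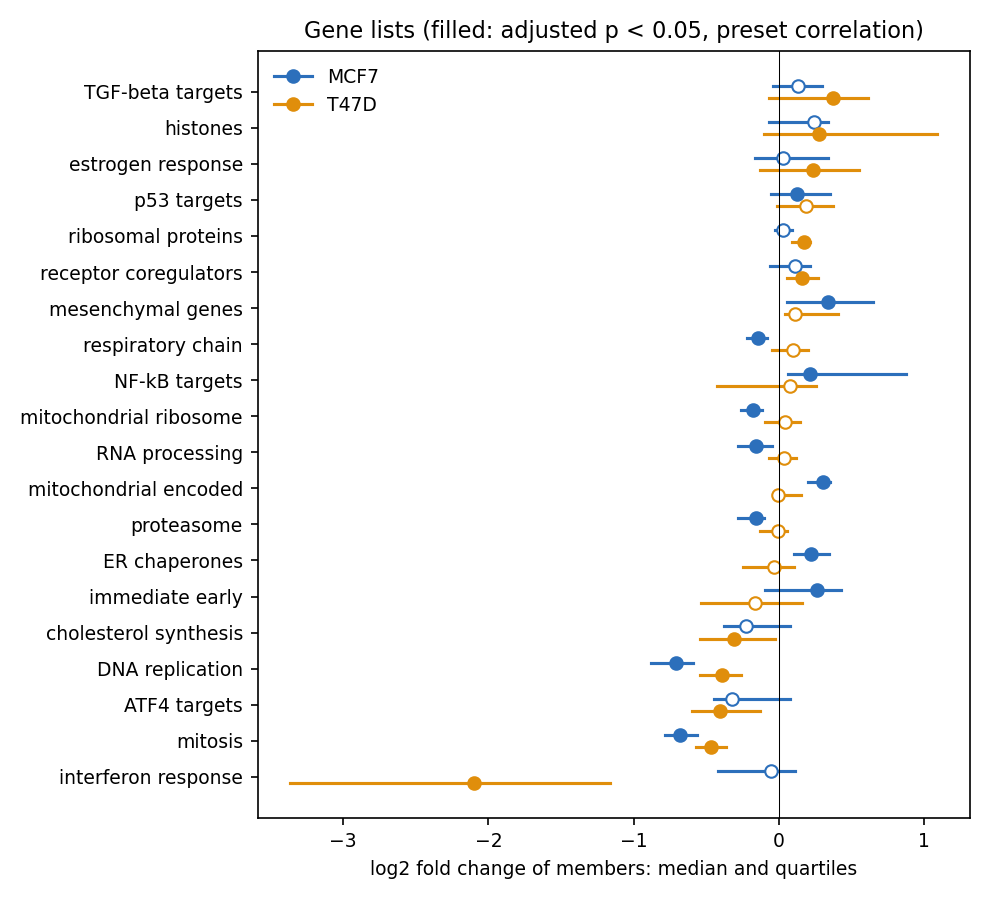
Median and quartiles of the members' log2 fold changes on the horizontal axis, for gene lists called in at least 1 line, in MCF7 (blue) and T47D (orange), with filled points for lists that passed camera's test with a preset correlation. The interferon list has a median of -2.10 in T47D and -0.05 in MCF7.

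Inflammatory and metabolic lists were among those that did not pass camera's test in T47D. Of 25 luminal identity genes, 1 rose, 2 fell and 22 did not pass (median 0.08, adjusted p = 0.728). Of 32 nuclear receptors, 7 rose, 4 fell and 21 did not pass (median -0.07, adjusted p = 0.728). Of 16 reported NR2C2 targets and partners, 1 rose, 3 fell and 12 did not pass (median -0.05, adjusted p = 0.615). Of 29 p53 targets, 8 rose, 5 fell and 16 did not pass (median 0.19, adjusted p = 0.138). Of 25 apoptosis regulators, 7 rose, 4 fell and 14 did not pass (median 0.06, adjusted p = 0.422). Of 14 NF-kB targets, 1 rose, 3 fell and 10 did not pass (median 0.07, adjusted p = 0.886). Of 23 immediate early genes, 0 rose, 4 fell and 19 did not pass (median -0.17, adjusted p = 0.314). Of 33 fatty acid metabolism genes, 2 rose, 7 fell and 24 did not pass (median -0.09, adjusted p = 0.309). Of 25 endoplasmic reticulum chaperones, 2 rose, 6 fell and 17 did not pass (median -0.03, adjusted p = 0.422). Of 21 antioxidant genes, 1 rose, 5 fell and 15 did not pass (median -0.08, adjusted p = 0.484). Of 28 hypoxia and glycolysis genes, 8 rose, 4 fell and 16 did not pass (median 0.09, adjusted p = 0.314). Of 38 nuclear-encoded respiratory chain genes, 2 rose, 1 fell and 35 did not pass (median 0.09, adjusted p = 0.484). For NF-kB targets the mean was -0.11 and the test pointed down.

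The remaining lists did not pass in T47D either. Of 15 mitochondrially encoded genes, 0 rose, 0 fell and 15 did not pass (median -0.00, adjusted p = 0.863). Of 28 ribosome assembly genes, 1 rose, 1 fell and 26 did not pass (median -0.03, adjusted p = 0.615). Of 35 mitochondrial ribosomal proteins, 0 rose, 3 fell and 32 did not pass (median 0.04, adjusted p = 0.863). Of 32 RNA processing factors, 0 rose, 1 fell and 31 did not pass (median 0.03, adjusted p = 0.728). Of 15 small RNA machinery genes, 6 rose, 3 fell and 6 did not pass (median 0.27, adjusted p = 0.314). Of 31 proteasome subunits, 0 rose, 0 fell and 31 did not pass (median -0.01, adjusted p = 0.615). Of 28 autophagy and lysosome genes, 3 rose, 7 fell and 18 did not pass (median -0.00, adjusted p = 0.728). Of 15 mesenchymal genes, 3 rose, 2 fell and 10 did not pass (median 0.11, adjusted p = 0.314). Of 12 basal epithelial genes, 3 rose, 1 fell and 8 did not pass (median -0.08, adjusted p = 0.921). Of 8 fibroblast markers, 2 rose, 0 fell and 6 did not pass (median 0.25, adjusted p = 0.453). Of 3 endothelial markers, 0 rose, 1 fell and 2 did not pass (median -0.11, adjusted p = 0.314). Of 3 blood cell markers, 0 rose, 0 fell and 3 did not pass (median -0.49, adjusted p = 0.58). Some of these lists passed under alternatives, given with adjusted p and the range over all alternatives in parentheses. They were p53 targets 0.0496 with the stricter filter and 0.0185 by fry (0.0185 to 0.658) and endoplasmic reticulum chaperones 0.0219 by fry (0.0219 to 0.952). Also passing were antioxidant genes 0.0185 by fry (0.0185 to 0.901) and hypoxia and glycolysis genes 0.0219 by fry (0.0219 to 0.779). Next came endothelial markers 0.0412 by fry (0.0412 to 0.957). Median, mean and test differed in sign for mitochondrially encoded genes (mean 0.04, test up), mitochondrial ribosomal proteins (mean -0.05, test down) and basal epithelial genes (mean -0.01, test up). The most abundant markers of other cell types in siScramble were COL1A1 at 50.6 CPM, ENG at 24.5 CPM and CD74 at 44.2 CPM.

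In T47D, 3834 of 15661 tested genes changed at adjusted p under 0.05 by edgeR with Benjamini-Hochberg adjustment, 1755 higher and 2079 lower. Of these, 609 changed by at least 2-fold, 235 higher and 374 lower. The groups did not overlap in 41.2% of tested genes, where chance gives 10%. With the replicate number as a block the count was 7334, 3625 higher and 3709 lower. The count was 2409 without T47D siScramble 2 and 2308 without T47D siScramble 3. Without T47D siScramble 1, 2 and 3 in turn, 1144, 1101 and 982 genes were higher. The genes lower numbered 1308 without T47D siScramble 2 and 1326 without T47D siScramble 3.

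Genes of the estrogen receptor programme were named whatever their result. ESR1, the estrogen receptor, rose in both lines, from 271 ± 18.2 to 348 ± 7.27 CPM in MCF7 and from 217 ± 10.2 to 323 ± 47.8 CPM in T47D (adjusted p = 0.0113 and 0.00499 by edgeR with Benjamini-Hochberg adjustment). PGR, the progesterone receptor and an estrogen receptor target, rose in T47D (0.55, SE 0.10, adjusted p = 0.00319). In MCF7 its log2 fold change was 0.38 (SE 0.14), with adjusted p = 0.104. The pioneer factor FOXA1 had 0.04 (SE 0.07) in MCF7 and 0.23 (SE 0.10) in T47D, with adjusted p = 0.749 and 0.119. GATA3 had 0.24 (SE 0.08) and 0.22 (SE 0.10), with adjusted p = 0.0761 and 0.158. NR2C1, the closest relative of NR2C2, had -0.33 (SE 0.11) and -0.12 (SE 0.09), with adjusted p = 0.0763 and 0.383. NR2C2AP, an NR2C2-associated protein, fell in MCF7 (-0.50, SE 0.11, adjusted p = 0.0127) and had -0.22 (SE 0.11) in T47D (adjusted p = 0.151).

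Several of these calls depended on 1 library or 1 setting. In MCF7, ESR1 had adjusted p = 0.0574 without MCF7 siScramble 1, 0.0811 without MCF7 siNR2C2 1 and 0.0575 without MCF7 siNR2C2 3 (over all alternatives 0.00103 to 0.0811). NR2C2AP had 0.0723 without MCF7 siNR2C2 1 and 0.0598 without MCF7 siNR2C2 3 (2.03e-04 to 0.0723). Without MCF7 siScramble 2, GATA3 had adjusted p = 0.0102 (0.0102 to 0.245) and PGR 0.0152. With no filter on low counts PGR had 0.00211 (0.00211 to 0.318). NR2C1 had 0.0356 in a fit over all 12 libraries (0.0356 to 0.212). In T47D without siNR2C2 1, FOXA1 had adjusted p = 0.00579 and GATA3 0.016. With the replicate number as a block in T47D, FOXA1 had 0.00252 (0.00252 to 0.332), GATA3 0.00688 (0.00688 to 0.432) and NR2C2AP 0.0347 (0.0347 to 0.398). FOXA1 overlaps TTC6, ESR1 overlaps SYNE1 and NR2C2AP overlaps RFXANK in the annotation.

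Many of the same genes changed in both lines. Besides NR2C2, ANTXR1 (-2.56 in MCF7, -3.01 in T47D), TMEM30A (-1.82 in MCF7, -2.39 in T47D), MINPP1 (-1.89 in MCF7, -1.89 in T47D), SERTAD4 (-2.04 in MCF7, -1.89 in T47D) and RECQL (-1.72 in MCF7, -2.00 in T47D) fell in both. The 3' UTRs of TMEM30A, MINPP1, SERTAD4 and RECQL hold the 7-mer CTTAGCT, treated under other observations, and that of ANTXR1 does not. SLC19A2, a thiamine transporter, rose from 110.5 ± 18.9 to 291 ± 48.1 CPM in MCF7 and from 33.1 ± 3.17 to 64.8 ± 11.2 CPM in T47D. The p53 target BTG2 (1.01 in MCF7, 0.96 in T47D) rose in both lines, as did YPEL2 (1.00 in MCF7, 1.02 in T47D), SYBU (0.92 in MCF7, 1.00 in T47D), SYNPO (0.92 in MCF7, 1.95 in T47D) and PDCD4-AS1 (1.32 in MCF7, 1.92 in T47D). Over 14116 genes tested in both, 432 rose in both lines, where independent lists would share 112. A further 696 fell in both, where independent lists would share 152. Fisher's exact test (two-sided) gave p = 1.78e-164 for the former and p = 1e-300, the smallest value written, for the latter. A further 23 genes were higher in MCF7 and lower in T47D, and 15 the opposite, where independent lists would share 133 and 127. Fold changes correlated across genes with Pearson's r of 0.49 and Spearman's rho of 0.499, and genes are not independent replicates.

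The 1128 genes shared in direction, among them SLC19A2 and ANTXR1, became 2066 with the replicate number as a block (898 higher, 1168 lower). The count was 693 without MCF7 siScramble 1, 499 without MCF7 siNR2C2 1, 730 without MCF7 siNR2C2 2 and 551 without MCF7 siNR2C2 3. Without these libraries in turn, 224, 149, 271 and 171 genes were higher. Without MCF7 siNR2C2 1, 2 and 3 in turn, 350, 459 and 380 were lower.

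**Figure D4:**
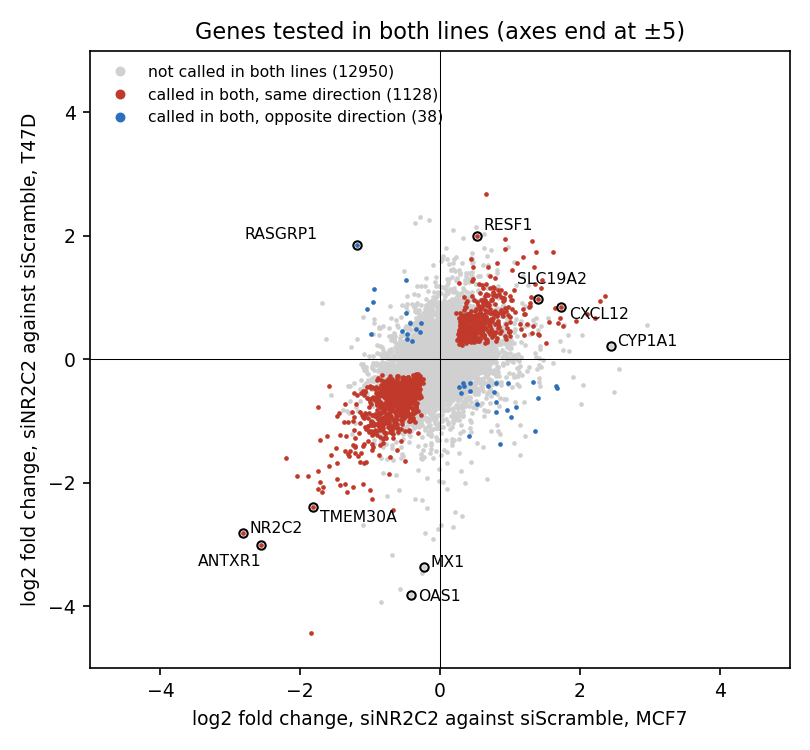
Log2 fold changes of 14116 genes in MCF7 (horizontal) and T47D (vertical), with colours for genes called in both lines in the same direction (1128) and in opposite directions (38), and labels for some genes named in the text. MX1 is at -3.37 in T47D and -0.23 in MCF7.

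The response to siNR2C2 differed between the lines for interferon-stimulated genes. The log2 fold change in T47D minus that in MCF7 was -3.09 (SE 0.26) for MX1, -3.35 (SE 0.36) for OAS1, -2.86 (SE 0.24) for IFITM1, -2.77 (SE 0.30) for ISG15, -2.64 (SE 0.23) for IRF7 and -1.34 (SE 0.12) for STAT1. In MCF7 none of these 6 passed the test. MX1 had 2.72 ± 0.234 CPM in MCF7 siScramble, against 329.9 ± 67.5 in T47D. RASGRP1, an activator of Ras, fell in MCF7 (-1.19) and rose in T47D (1.85). The imprinted RNA H19 (-0.96 and 0.94) and the matrix protein NPNT (-0.49 and 1.29) did so too. The differences were 3.09 (SE 0.28), 1.95 (SE 0.17) and 1.83 (SE 0.17). Those of RESF1 1.52 (SE 0.13), C1QTNF6 1.32 (SE 0.14) and TRAM2 1.07 (SE 0.12) were also positive. Interaction p-values adjusted over 17511 genes by edgeR with Benjamini-Hochberg adjustment were 5.70e-06 for MX1, 9.74e-05 for OAS1, 7.76e-06 for STAT1, 7.73e-06 for RASGRP1 and 6.02e-06 for H19. The fall of NPNT in MCF7 had adjusted p = 0.0601 without MCF7 siScramble 1, 0.0849 without MCF7 siNR2C2 1, 0.0903 without MCF7 siNR2C2 2 and 0.129 without MCF7 siNR2C2 3 (over all alternatives 0.00191 to 0.129). IFITM1 overlaps IFITM2, STAT1 overlaps GLS, TRAM2 overlaps EFHC1 and NPNT overlaps INTS12.

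STAT2 fell in both lines, in MCF7 from 40.9 ± 10.3 to 19.2 ± 3.49 CPM. Its difference was -0.53 (SE 0.21), with adjusted p = 0.21 by edgeR with Benjamini-Hochberg adjustment. That p was 0.00437 with the replicate block, 0.0234 with no filter on low counts and 0.019 without MCF7 siScramble 2 (over all alternatives 0.00437 to 0.363). The differences of NR2C2 (0.06, adjusted p = 0.943), ESR1 (0.26, adjusted p = 0.438), PGR (0.22, adjusted p = 0.608), FOXA1 (0.24, adjusted p = 0.398), GATA3 (0.03, adjusted p = 0.968), NR2C1 (0.26, adjusted p = 0.419) and NR2C2AP (0.33, adjusted p = 0.295) did not pass the test. The sign of the differences of NR2C2 and GATA3 turned under other filters and without single libraries. Without both MCF7 siScramble 2 and T47D siNR2C2 1, those of ESR1 and FOXA1 had adjusted p = 0.00776 (0.00776 to 0.851) and 0.0359 (0.0359 to 0.882).

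In all, 545 of 17511 genes, MX1 and H19 among them, differed in response, 279 higher and 266 lower in T47D than in MCF7. With RLE in place of TMM scaling these were 191 and 297. With the replicate number as a block 1960 differed, 1185 higher and 775 lower, and by DESeq2 841. The count was 354 without MCF7 siScramble 1, 243 without MCF7 siNR2C2 1, 287 without MCF7 siNR2C2 3, 326 without T47D siScramble 1, 228 without T47D siScramble 2, 247 without T47D siScramble 3 and 305 without T47D siNR2C2 3. Genes higher numbered 117 and 169 without MCF7 siScramble 1 and 3, and 75, 102 and 89 without MCF7 siNR2C2 1, 2 and 3. They numbered 149, 103 and 106 without T47D siScramble 1, 2 and 3, and 151 without T47D siNR2C2 3. Genes lower numbered 516 without MCF7 siScramble 2, 168 without MCF7 siNR2C2 1, 177 without T47D siScramble 1, 125 without T47D siScramble 2, 141 without T47D siScramble 3 and 154 without T47D siNR2C2 3. Without both MCF7 siScramble 2 and T47D siNR2C2 1, a choice made after seeing the data, 1658 differed.

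Interferon-stimulated genes also differed between the lines as a list. Their median difference was -1.71, with 0 up, 25 down and 16 not called (0 and 33 over the list alone). For them camera gave adjusted p = 1.45e-40 (0.0898 with an estimated correlation). Endoplasmic reticulum chaperones had a median difference of -0.28, with 0 up, 3 down and 22 not called (0 and 9 over the list alone). Camera gave this list adjusted p = 7.00e-06 (0.608 with an estimated correlation). Immediate early genes had a median difference of -0.34, with 0 up, 4 down and 21 not called (0 and 6 over the list alone). For immediate early genes, camera gave adjusted p = 1.23e-04 (0.761 with an estimated correlation). NF-kB targets had a median difference of -0.29, with 0 up, 5 down and 9 not called (0 and 6 over the list alone). For NF-kB targets, camera gave adjusted p = 0.00297 (0.682 with an estimated correlation). Autophagy and lysosome genes had a median difference of -0.18, with 0 up, 2 down and 26 not called (0 and 3 over the list alone). Camera gave them adjusted p = 0.0108 (0.682 with an estimated correlation). ATF4 response genes had a median difference of -0.14, with 0 up, 2 down and 27 not called (0 and 2 over the list alone). For ATF4 response genes, camera gave adjusted p = 0.0241 (0.761 with an estimated correlation). Mitochondrially encoded genes had a median difference of -0.26, with 0 up, 1 down and 14 not called (0 and 1 over the list alone). Camera gave them adjusted p = 0.033 (0.761 with an estimated correlation). In MCF7 the mean log2 deviation of the ATF4 response genes was -0.34, 0.72 and -0.21 in siScramble replicates 1, 2 and 3 and -0.08, -0.14 and 0.04 in siNR2C2, so siScramble 2 stood apart and set the direction in MCF7. Without it the difference had adjusted p = 4.07e-11 (over all alternatives 4.07e-11 to 0.76). Without 1 library the ATF4 call ended at adjusted p = 0.577 without MCF7 siScramble 1, 0.321 without MCF7 siScramble 3, 0.136 without MCF7 siNR2C2 3 and 0.0591 without T47D siScramble 3. The mitochondrial call ended at 0.069 and 0.297 without MCF7 siScramble 2 and 3, and 0.117 and 0.218 without MCF7 siNR2C2 1 and 3. It ended at 0.128 and 0.116 without T47D siScramble 1 and 3, and 0.189 without T47D siNR2C2 2.

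Cell cycle lists, called lower in both lines, were less negative in T47D as lists. DNA replication genes had a median difference of 0.38, with 1 up, 0 down and 35 not called (3 and 0 over the list alone). For DNA replication genes, camera gave adjusted p = 6.16e-04 (0.761 with an estimated correlation). Mitotic genes had a median difference of 0.24, with 1 up, 0 down and 34 not called (1 and 0 over the list alone). For mitotic genes, camera gave adjusted p = 0.00218 (0.761 with an estimated correlation). Nuclear-encoded respiratory chain genes had a median difference of 0.24, with 1 up, 0 down and 37 not called (4 and 0 over the list alone). Camera gave this list adjusted p = 1.65e-05 (0.761 with an estimated correlation). Mitochondrial ribosomal proteins had a median difference of 0.24, with 0 up, 0 down and 35 not called (0 and 0 over the list alone). Camera gave them adjusted p = 0.00127 (0.761 with an estimated correlation). RNA processing factors had a median difference of 0.21, with 3 up, 0 down and 29 not called (4 and 0 over the list alone). Camera gave them adjusted p = 0.00146 (0.525 with an estimated correlation). The call on DNA replication genes ended at adjusted p = 0.194 without MCF7 siScramble 3, and that on mitotic genes at 0.284 without MCF7 siScramble 3.

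The lists of ribosomal proteins, proteasome subunits and histones were called more positive in T47D by camera with a preset correlation. Ribosomal proteins had a median difference of 0.20, with 0 up, 0 down and 58 not called (0 and 0 over the list alone). For ribosomal proteins, camera gave adjusted p = 0.00275 (0.761 with an estimated correlation). Proteasome subunits had a median difference of 0.19, with 0 up, 0 down and 31 not called (0 and 0 over the list alone). For proteasome subunits, camera gave adjusted p = 0.0108 (0.761 with an estimated correlation). Histone genes had a median difference of 0.25, with 3 up, 0 down and 15 not called (5 and 0 over the list alone). For histone genes, camera gave adjusted p = 0.0241 (0.761 with an estimated correlation). In T47D siNR2C2 1 the mean log2 deviation was 0.36 for ribosomal proteins, 0.40 for histones and 0.17 for the proteasome. The call on ribosomal proteins ended at adjusted p = 0.13 without MCF7 siScramble 2 and 0.62 without T47D siNR2C2 1. That on the proteasome ended at 0.321 without MCF7 siScramble 3, 0.0747 without MCF7 siNR2C2 2, 0.0725 without T47D siScramble 2 and 0.173 without T47D siNR2C2 1. That on histones ended at 0.18 without MCF7 siScramble 2, 0.0696 without MCF7 siNR2C2 3, 0.0687 without T47D siScramble 3 and 0.219 without T47D siNR2C2 1. Without both T47D siNR2C2 1 and MCF7 siScramble 2, the ribosomal proteins had adjusted p = 0.774 in the other direction and the histones 0.39.

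For estrogen receptor targets and other lists the difference between the lines did not pass camera's test. Of 39 estrogen receptor targets, 5 differed upward, 2 downward and 32 did not pass (median 0.11, adjusted p = 0.187). Of 25 luminal identity genes, 0 differed upward, 1 downward and 24 did not pass (median 0.00, adjusted p = 0.721). Of 24 receptor coregulators, 0 differed upward, 0 downward and 24 did not pass (median 0.05, adjusted p = 0.28). Of 36 nuclear receptors, 1 differed upward, 0 downward and 35 did not pass (median 0.02, adjusted p = 0.269). Of 17 reported NR2C2 targets and partners, 0 differed upward, 1 downward and 16 did not pass (median -0.00, adjusted p = 0.269). Of 30 p53 targets, 1 differed upward, 1 downward and 28 did not pass (median 0.05, adjusted p = 0.527). Of 25 apoptosis regulators, 2 differed upward, 1 downward and 22 did not pass (median 0.07, adjusted p = 0.835). Of 24 cholesterol synthesis genes, 0 differed upward, 1 downward and 23 did not pass (median -0.04, adjusted p = 0.169). Of 34 fatty acid metabolism genes, 1 differed upward, 0 downward and 33 did not pass (median -0.08, adjusted p = 0.366). The tests of luminal identity genes (mean -0.01), nuclear receptors (mean -0.08) and p53 targets (mean 0.03) pointed down, against the sign of their medians.

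The difference did not pass for the remaining lists either. Of 25 antioxidant genes, 0 differed upward, 2 downward and 23 did not pass (median -0.15, adjusted p = 0.0896). Of 30 hypoxia and glycolysis genes, 2 differed upward, 0 downward and 28 did not pass (median 0.20, adjusted p = 0.0751). Of 30 ribosome assembly genes, 0 differed upward, 0 downward and 30 did not pass (median 0.12, adjusted p = 0.269). Of 15 small RNA machinery genes, 1 differed upward, 0 downward and 14 did not pass (median 0.14, adjusted p = 0.269). Of 18 mesenchymal genes, 0 differed upward, 1 downward and 17 did not pass (median 0.09, adjusted p = 0.0751). Of 15 basal epithelial genes, 0 differed upward, 1 downward and 14 did not pass (median -0.09, adjusted p = 0.269). Of 20 TGF-beta response genes, 1 differed upward, 0 downward and 19 did not pass (median 0.16, adjusted p = 0.366). Of 9 fibroblast markers, 0 differed upward, 0 downward and 9 did not pass (median -0.13, adjusted p = 0.901). Of 5 endothelial markers, 0 differed upward, 0 downward and 5 did not pass (median -0.05, adjusted p = 0.366). Of 3 blood cell markers, 0 differed upward, 0 downward and 3 did not pass (median -0.45, adjusted p = 0.291). The mean of the mesenchymal genes was -0.01 and their test pointed down. Some of these lists passed under alternatives, given with adjusted p and the range over all alternatives in parentheses. Both that stand apart are MCF7 siScramble 2 and T47D siNR2C2 1. They were reported NR2C2 targets and partners 0.0194 with no filter (0.0194 to 0.76) and antioxidant genes 0.0364 with no filter, 0.0476 with a replicate block, 0.0464 without MCF7 siScramble 1, 0.0127 without MCF7 siScramble 3, 0.0118 without MCF7 siNR2C2 2 and 0.0476 without T47D siNR2C2 1 (0.0118 to 0.76). Also passing were hypoxia and glycolysis genes 0.0323 with no filter, 0.0432 with the stricter filter, 0.00473 with a replicate block, 0.0348 without MCF7 siScramble 1, 0.00288 without MCF7 siScramble 3, 5.84e-05 without MCF7 siNR2C2 2 and 0.0476 without T47D siNR2C2 1 (5.84e-05 to 0.819) and basal epithelial genes 0.0448 with no filter and 0.0385 without MCF7 siNR2C2 3 (0.0385 to 0.76). Next came ribosome assembly genes 0.0394 without MCF7 siScramble 2 and 0.0489 without both that stand apart (0.0394 to 0.798) and mesenchymal genes 0.0151 without MCF7 siScramble 2, 0.0432 without MCF7 siNR2C2 3, 0.0372 without T47D siScramble 1, 0.0122 without T47D siNR2C2 2 and 0.0281 without both that stand apart (0.0122 to 0.76). Then came cholesterol synthesis genes 0.0114 without MCF7 siScramble 3 and 0.0476 without T47D siNR2C2 1 (0.0114 to 0.991) and estrogen receptor targets 0.0218 without T47D siNR2C2 1 (0.0218 to 0.76). After these came receptor coregulators 0.00286 without T47D siNR2C2 1 and 0.00161 without both that stand apart (0.00161 to 0.798) and small RNA machinery genes 0.034 without T47D siNR2C2 1 and 0.0214 without both that stand apart (0.0214 to 0.76). Last came nuclear receptors 0.0387 without T47D siNR2C2 2 (0.0387 to 0.769).

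The authors' deposited table gave 2520 genes at adjusted p under 0.05 in MCF7 and 3844 in T47D. Of these, 2182 and 3580 were also called by edgeR here, each in the same direction. With an absolute log2 fold change of at least 1 as well, the authors' deposited table gave 278 and 552. For MX1 in T47D the authors' deposited table listed a log2 fold change of -3.35, and for PLAT in MCF7 2.98.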

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

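The interaction test was planned, while the tests of explanations and the splits of the libraries reported here were chosen after the results were seen. The interaction of siRNA and line picked out results whose response differed between T47D and MCF7, 545 genes in all by edgeR with Benjamini-Hochberg adjustment. Of 100 splits of the libraries, the real one and others drawn at random, only the real one gave as many, and the highest other gave 500. That split kept the real groups of T47D and mixed those of MCF7, and the next, with 498 genes, did the reverse. The real groups with the labels exchanged in 1 line were not among those drawn. All 84 splits that mixed the groups of both lines gave 0. This share argues against a chance arrangement of the libraries with no effect of the siRNA in either line. It cannot test whether the lines responded alike. Splits that kept the real groups of MCF7 alone gave 1 to 498 genes, and those of T47D alone 116 to 500. The splits that kept the real groups of 1 line set its response against a mixture, and do not tell how many genes would differ between lines that respond alike.

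Among the named genes, H19 (1.95), RASGRP1 (3.09), RESF1 (1.52), NPNT (1.83), C1QTNF6 (1.32), TRAM2 (1.07), MX1 (-3.09), OAS1 (-3.35), IFITM1 (-2.86), ISG15 (-2.77), IRF7 (-2.64) and STAT1 (-1.34) had the smallest interaction p of each sign, as T47D minus MCF7 in log2. All 12 kept their call without each of the 12 libraries. Of the other named genes, 40 also differed, 29 lower and 11 higher in T47D. Those that kept the call without each library were ATF3 (-1.38), CD44 (-1.01), CXCL12 (-0.83), CYP1A1 (-2.19), DNAJB9 (-1.21), DUSP4 (-1.61), FSCN1 (1.77), H2AC6 (1.13), H3C10 (1.29), IFI6 (-3.11), MAFB (-1.39), OAS3 (-1.71) and UBE2L6 (-0.83).

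For 27 named genes the call on the difference ended without at least 1 library. Each is given with its difference, then in parentheses the number of the 12 libraries whose omission ended the call, the highest adjusted p and the library left out for it. They were AEN -0.57 (8, 0.153, T47D siScramble 3), ATG13 -0.68 (2, 0.0797, T47D siScramble 2), BAMBI 0.80 (1, 0.0552, MCF7 siNR2C2 1), BIRC3 -1.14 (10, 0.13, MCF7 siNR2C2 3), DDIT3 -1.10 (9, 0.12, T47D siNR2C2 1), DDX60 -2.56 (1, 0.13, MCF7 siNR2C2 1) and ETV4 -2.54 (1, 0.0652, T47D siNR2C2 3). Next were GABARAPL1 -0.76 (2, 0.0833, T47D siScramble 2), H2AC13 1.44 (2, 0.0591, MCF7 siNR2C2 3), HSPB8 0.49 (11, 0.182, MCF7 siNR2C2 1), ICAM1 -1.06 (3, 0.078, T47D siScramble 2), IFI27 -3.04 (3, 0.0731, MCF7 siNR2C2 1), IFIT1 -3.16 (1, 0.0516, T47D siNR2C2 1) and MT-RNR1 -0.61 (9, 0.114, MCF7 siNR2C2 1). Then followed NDC80 0.56 (9, 0.132, MCF7 siNR2C2 1), NDUFA8 0.49 (10, 0.152, MCF7 siNR2C2 1), OAS2 -2.45 (6, 0.166, MCF7 siNR2C2 1), PLAT -2.56 (9, 0.231, T47D siScramble 1), PRPF4 0.46 (10, 0.258, MCF7 siNR2C2 3), RELB -1.21 (4, 0.0779, T47D siScramble 3) and SPRY4 -1.69 (1, 0.0643, T47D siScramble 3). The last were SYNPO 1.08 (8, 0.0832, MCF7 siNR2C2 1), TNF -2.34 (6, 0.0846, T47D siScramble 2), TNFAIP3 -1.56 (1, 0.0504, T47D siScramble 1), TRPC6 -1.59 (8, 0.171, T47D siScramble 2), VDR 0.80 (4, 0.0842, MCF7 siNR2C2 1) and ZFP36 -0.80 (1, 0.0596, T47D siScramble 2).

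Camera's test of the interaction picked out 15 lists, given here with the median difference. Lower in T47D were interferon-stimulated genes (-1.71), immediate early genes (-0.34), NF-kB targets (-0.29), endoplasmic reticulum chaperones (-0.28), mitochondrially encoded genes (-0.26), autophagy and lysosome genes (-0.18) and ATF4 response genes (-0.14). Higher in T47D were DNA replication genes (0.38), histone genes (0.25), nuclear-encoded respiratory chain genes (0.24), mitotic genes (0.24), mitochondrial ribosomal proteins (0.24), RNA processing factors (0.21), ribosomal proteins (0.20) and proteasome subunits (0.19). None of the 15 was called with an estimated correlation. Of 100 splits, 24 gave as many lists and the highest other gave 25, so a chance arrangement of the libraries is not excluded for the number of lists.

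Interferon-stimulated genes fell as a list in T47D and not in MCF7, where 2 single members, STAT2 and OAS3, fell. The MCF7 call on OAS3 (-0.67) ended at adjusted p = 0.115 and 0.073 without MCF7 siScramble 1 and 3. That p was 0.0946, 0.125 and 0.122 without MCF7 siNR2C2 1, 2 and 3, and 0.0554 by limma-voom (over all alternatives 2.33e-08 to 0.125). Members with an annotated 3' UTR and no 7-mer CTTAGCT had a median of -1.93 in T47D. That site in their own transcripts does not explain the list. In siScramble the list's median level was 3.81 CPM in MCF7 and 30.7 in T47D. The 19 members with at least 5 CPM in MCF7 siScramble had a median difference of -1.225 (quartiles -1.85 and -0.76), negative in all. Too few reads do not explain these, but an interferon response already low in MCF7 could, and stays open. So does one raised by transfection or by siScramble, and lowered in siNR2C2, since 0 libraries had no siRNA. Dependence on NR2C2 may also differ between the lines, or upstream genes may be silenced. Neither was tested. Among upstream genes with the 7-mer in the 3' UTR, IFNAR1 fell in T47D (-0.40), MAVS did not pass and JAK1 rose (0.43). STAT2 holds only the shifted 7-mer, in its coding sequence.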

How the results depend on the processing

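All alternatives were planned except the omission of 2 libraries together and of genes with a sequence in the 3' UTR, which were chosen after seeing the data. NR2C2 kept its direction and call under all 14 alternatives in each line. Its log2 fold change ran from -2.95 to -2.63 in MCF7 and from -2.85 to -2.74 in T47D when 1 library was left out. Of 264 called results on named genes, 179 kept direction and call under every alternative. In 3946 comparisons, 3598 kept the call, 348 lost it and 0 turned in sign. Of 51 results not called, 16 stayed so under every alternative, 13 of them with the same sign throughout, and in 754 comparisons 105 gained a call and 17 turned in sign. The 37 calls on lists held in 436 of 549 comparisons, were lost in 112 and turned in 1.

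When 1 library was left out, the count in MCF7 ran from 782 to 4199 (higher 345 to 2018, lower 437 to 2181, at least 2-fold 204 to 472). In T47D it ran from 2308 to 5051 (higher 982 to 2417, lower 1308 to 2634, at least 2-fold 534 to 657). For the difference it ran from 228 to 785 (higher 75 to 397, lower 125 to 516, at least 2-fold 145 to 269). In both lines it ran from 499 to 1633 (higher 149 to 640, lower 350 to 993). Called lists numbered 6 to 15 in MCF7, 7 to 10 in T47D and 12 to 18 for the difference. Fewer libraries allow fewer calls, but some omissions raised a count, and the cause was not tested.

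With the replicate number as a block, 7334 genes were called in T47D (3625 higher, 3709 lower). For the difference 1960 were called (1185 higher, 775 lower, 354 at least 2-fold), and 2066 in both lines (898 and 1168). In MCF7 the block gave 3317. There, libraries of the same number correlated at 0.08, 0.21 and 0.34, each best with its own number, which is only a hint of pairing. The cause was not tested.

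Without MCF7 siScramble 2 and T47D siNR2C2 1 together, 4199 genes were called in MCF7 (2018 higher, 2181 lower), 1658 for the difference (1119 and 539) and 2042 in both lines (828 and 1214). The difference of the ribosomal protein list turned in direction, with adjusted p = 0.774. DESeq2 called 841 genes for the difference, 449 of them lower. The stricter filter gave 171 higher, and no filter 461 lower. The cause was not tested.

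Camera with an estimated correlation called 0 lists in MCF7, 0 in T47D and 0 for the difference, and fry called 0, 12 and 3. Fry does not compare a list with other genes. In the authors' deposited table, calls with an absolute log2 fold change of at least 1 numbered 278 and 552, as the added threshold allows fewer. Leaving out genes with a site in the 3' UTR or with no annotated 3' UTR left 700 genes lower in MCF7 and 1253 in T47D, since fewer genes remained.

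Signs turned only for uncalled values near 0 among the named genes. The difference of GATA3 was -0.0106 with RLE and by DESeq2, -0.0354 with no filter and -0.0421 with the stricter filter. It ran from -0.10 to 0.12 without 1 library. That of NR2C2 was -0.00268 with no filter and -0.00978 with the stricter filter, and ran from -0.20 to 0.12 without 1 library. ISG15 in MCF7 ran from -0.28 to 0.12 without 1 library. The cause was not tested.

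Scaling by RLE moved the median of all genes by less than 0.01 in each line. Depth limits what can be seen of rare transcripts, and in simulated data 23.9% of genes whose response differed 1.5-fold were recovered.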

Other observations

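The tests reported here were chosen after the results were seen, except that of GC content and transcript length, which was written before.

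Nuclear receptors and reported NR2C2 targets did not pass as lists in either line, but single members changed. Of the nuclear receptors 4 rose and 3 fell in MCF7, and 7 and 4 in T47D. Of the reported targets 3 rose and 3 fell in MCF7, and 1 and 3 in T47D. In T47D ESR1 and PGR rose, and in MCF7 the reported targets CYP1A1 and GADD45A. NR4A2 rose in MCF7 (0.48 (SE 0.10), adjusted p = 0.011), a call that ended at 0.0735 without MCF7 siNR2C2 1 and 0.0603 without MCF7 siNR2C2 3 (over all alternatives 7.82e-04 to 0.0735). The retinoic acid receptor RARG fell in MCF7 (-0.99 (SE 0.10), adjusted p = 3.56e-04) and in T47D (-1.16 (SE 0.11), adjusted p = 1.06e-04) by edgeR. EZH2, a histone methyltransferase reported as an NR2C2 target, fell in MCF7 (-0.69 (SE 0.09)) and T47D (-0.56 (SE 0.10)). In T47D the glucocorticoid receptor NR3C1 fell (-0.68 (SE 0.11)), and so did HNF4G (-2.04 (SE 0.35)). In MCF7 the vitamin D receptor VDR fell (-0.72 (SE 0.16)), a call that ended at adjusted p = 0.0837 without MCF7 siNR2C2 1 and 0.0702 without MCF7 siNR2C2 2 (over all alternatives 2.28e-04 to 0.0837). The 3' UTRs of RARG, EZH2 and NR3C1 hold the 7-mer described next, and those of HNF4G and VDR do not.

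Genes whose 3' UTR held the 7-mer CTTAGCT were lower in both lines. Over all 7-mers in 3 transcript parts and both lines, it had the most negative t, -18.9 in MCF7 and -20.01 in T47D. Median log2 fold changes of genes with the 7-mer followed by A, the 7-mer alone, the 7-mer shifted by 1 base and none were -0.18, -0.09, -0.03 and 0.01 in MCF7 and -0.29, -0.14, -0.07 and 0.03 in T47D. Of genes that fell, 34.3% in MCF7 and 31.9% in T47D held a site, against 15.8% and 15.7% of tested genes, among genes with an annotated 3' UTR. The shares were 53.8% and 42.2% among genes lower by at least 2-fold, and 13.3% and 10.8% among genes that rose.

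Length or base composition of 3' UTRs does not account for this, since the lowest t among 419 reorderings of the 7-mer was -8.845 in MCF7 and -9.68 in T47D. A candidate explanation is silencing of other transcripts through the seed of the siRNA. NR2C2's coding sequence of 1848 bases holds the 7-mer followed by A once, at position 1002 from its start, and 0.515% of 13582 coding sequences do, or 1.14% of 4290 at least as long. The siRNA's sequence is not given in the sources used here, and no second siRNA or rescue was sequenced, so neither this nor an effect of NR2C2 loss through such sites was tested directly. Genes with the 7-mer in the 3' UTR may therefore have fallen through the siRNA rather than through NR2C2, as may genes downstream of them. Among genes named as lower these were TMEM30A, MINPP1, SERTAD4, RECQL, GALNT12, DEPDC1B, SREBF2, HMGCR, RAB31, PDIA3, GINS1, GINS2, FOXM1, IFIT1, RARG, EZH2, NR3C1, in MCF7 RASGRP1, and in T47D AEN and ATG13. In coding sequences too the 7-mer had the most negative t, -5.97 in MCF7 and -6.13 in T47D. CDC6 holds it there, followed by A, and TOP2A, CEBPG and DDX60 hold its shifted form in the 3' UTR. These may be affected as well. ANTXR1 holds neither the 7-mer nor its shifted form in any of the 3 parts.

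The fall of DNA replication and mitotic genes in both lines was weighed against technical causes. Among members without a site, the median nearest 0 over both lists and lines was -0.38, so a site in their own transcripts does not account for it. After removal of trends with GC content, length and level, the median nearest 0 was -0.39. Without any 1 library in MCF7 the highest adjusted p by camera with a preset correlation was 9.77e-10. For the DNA replication list, a mixed split of the libraries gave a lower unadjusted camera p than the real groups, 3.91e-18 against 2.16e-13 in MCF7 and 1.58e-09 against 3.39e-09 in T47D. For the mitotic list the lowest p of the mixed splits was higher, 1.98e-12 against 4.69e-18 and 4.51e-07 against 4.25e-13. Libraries thus also differed in replication genes within groups, for a reason not tested. Loss of NR2C2, and an indirect effect of the siRNA through other targets, may each be the cause, and these data do not separate them.

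Splits of the 6 libraries of a line into other groups of 3 number 10 with the real one, too few for a share under 0.05. The real split called 2280 genes in MCF7 and 3834 in T47D, 1 of 10 in each, and the highest other called 0. For lists, 5 of 10 splits called as many as the real 12 in MCF7 (highest other 17), and 7 of 10 as many as the real 10 in T47D (highest other 18). In T47D the 3 other splits that part libraries of the same number called 3, 9 and 5 lists and 0 genes. In MCF7 the same 3 splits called 2, 5 and 14 lists and 0 genes, so 1 of them exceeded the real 12. For genes changed in both lines, the real 1128 came from 1 of 100 splits and the highest other gave 0. Since each mixed split of a line called 0 genes, that 0 was fixed in advance, and this count of splits decides nothing.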
